A study of Mus musculus with 4 samples.

How the data were processed

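RNA of mouse pancreatic islets was sequenced in 4 libraries, 2 without and 2 with insulin depletion, and all 4 were analysed. Islets were isolated by collagenase digestion of the pancreas, RNA was purified with an RNeasy micro kit, and libraries were made with a KAPA mRNA kit, per the labels' protocols. The same protocol text describes dissociation to single cells for a Chromium run, and it does not say whether the islets of the bulk libraries were dissociated. The depleted libraries were treated with an insulin depletion panel of Jumpcode Genomics (DepleteX) within that library preparation, per the labels' protocols. The labels give neither how the panel cuts nor its guide sequences. The sites compared below rest on the general knowledge that such panels use CRISPR guides beside an NGG motif.

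The authors deposited 1 table of gene counts as whole numbers, with 55536 genes in rows and the 4 libraries in columns, and no normalization is applied to them. The deposited columns of the non-depleted libraries are noted under the unit expected counts only because an automated unit check took the word size in their headers for a size column. Their values are whole numbers on the same scale as the other columns and were treated as counts, so rounding changed nothing. That word is part of a tag that reads as size selection, which the insulin-depleted headers lack, and the labels do not mention size selection. The tools cutadapt 4.8 and STAR 2.7.11b and the genome builds GRCm38 and mm10, which are names of the same mouse assembly, are named without roles, per the submitters' processing notes. The counting program, its use of strand and its treatment of reads that map to several places are not given in the sources used here. These affect genes that overlap others and genes with near-identical copies. All 55536 gene identifiers and symbols matched those of the GENCODE M21 annotation of GRCm38, from which coordinates, biotypes and transcript sequences were taken. No row lacked a gene name.

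Low counts were mostly even. Among genes with 2 to 9 counts in a library, 80.9%, 80.01%, 84.01% and 81.4% had an even count in non-depleted replicates 1 and 2 and insulin-depleted replicates 1 and 2, and among genes with the highest counts 50.5 to 51.0% did. Such a pattern arises when both reads of a pair are counted, which no source used here states. Counts were used as deposited, and alternatives with counts in twos were added.

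Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, scaled by TMM (levels are given as CPM, counts scaled to the same total in each library), and fitted with estimateDisp and glmQLFit (robust) on group alone, with glmQLFTest for insulin-depleted over non-depleted. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Standard errors were taken from the log2 fold change and the test statistic, and 95% intervals from these and the moderated degrees of freedom. The common dispersion was 0.0291, a biological coefficient of variation of 17.1%. DESeq2 1.42.0, which gave no missing adjusted p, and limma-voom (limma 3.58.1) were alternatives. On simulated counts of 19010 genes, the edgeR step recovered 0 of 50 genes changed 1.5-fold, 3 of 50 changed 2-fold, 39 of 50 changed 4-fold and 47 of 50 changed 16-fold, with 4 false calls. This simulation drew each library independently. In it and in the next one, the changed genes were drawn only from genes with a mean of at least 5 CPM. A further simulation of 19198 genes held a term for the replicate number, as did its test. It recovered 36 of 50 genes changed 1.2-fold and 50 of 50 changed 2-fold, with 7 false calls.

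Shares of counts and genes detected were compared with exact two-sided permutation tests, whose smallest p with 2 against 2 libraries is 0.333. Shares of single libraries carry exact Clopper-Pearson 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only. A limit of 3 counts corresponds to 0.0593, 0.0496, 0.155 and 0.0461 CPM in non-depleted replicates 1 and 2 and insulin-depleted replicates 1 and 2. For genes detected, each library was thinned without replacement to 19316173 counts, the smallest total, and numbers were averaged over 20 thinnings. Replicates were compared by a chi-square test over genes with at least 20 counts in sum. The spread over genes was the SD of the difference between group means of log2 CPM, with a prior count of 2.

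Before the data were examined, the tests, 22 gene lists, the alternatives and the rule for named genes were fixed. The lists were the insulin genes, other islet peptide hormones, beta-cell identity, secretory granule and prohormone processing, the insulin and relaxin superfamily other than Ins1 and Ins2, and markers of alpha, delta and gamma, acinar, ductal, endothelial, stellate and fibroblast, immune, Schwann and erythroid cells. The others were mitochondrially encoded mRNAs, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, endoplasmic reticulum stress, immediate early and dissociation stress, the cell cycle, replication-dependent histones and nuclear-retained long noncoding RNAs. Lists with 3 or more tested members were tested with camera on log2 CPM with a preset correlation of 0.01, adjusted over the 21 lists left without the insulin genes, and also with an estimated correlation and with fry. Named genes were Ins1 and Ins2, the other islet hormones that passed the filter, and the 10 genes with the largest called rise and fall, both insulin-depleted libraries on the same side of both others and a mean of at least 5 CPM. Where fewer than 5 were called in a direction, as here, the 5 with the smallest p and a mean of at least 5 CPM took their place. The rule also took up to 2 genes of each list, the called ones or else the most abundant, and the 5 most abundant genes of each group.

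Alternatives were other size factors, total counts, insulin genes left out of the totals, other tools, other filters, no robust shrinkage, a test against a fold of 1.2, a model term for the replicate number, a correction for GC content, and leaving out each library in turn. Insulin-like cut sites were 20-base sequences beside an NGG motif, compared between annotated transcripts on both strands with up to 3 mismatches. Shared sequence was the share of a gene's 31-base stretches found in transcripts of another gene on either strand. Trends with GC content and transcript length were removed by least squares. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.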

Results

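The data were gene counts from bulk RNA sequencing of pancreatic islets, the hormone-secreting cell clusters of the pancreas, of male C57BL/6 mice aged 8 weeks. Libraries were made from polyadenylated RNA with or without a step that depletes insulin sequences during library preparation. There were 4 libraries, 2 non-depleted and 2 insulin-depleted, and the labels call the 2 of each group biological replicates. Every column name of the count table carries the same pair of codes, so it is open whether the replicates came from separate animals, and p-values measure the spread between these libraries. The 2 non-depleted columns were matched to their libraries because they lack the insulin-depletion tag and end in the replicate number. Their names also carry a tag that reads as size selection, which the insulin-depleted names lack, so any difference in size selection would be part of every group difference given here. The counts summed to 50605417 and 60528485 in non-depleted replicates 1 and 2. Insulin-depleted replicate 1 had 19316173 counts and insulin-depleted replicate 2 had 65030111.

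The first question was how much insulin sequence the depletion removed. Mice have 2 insulin genes, Ins1 and Ins2, both expressed by beta cells. Together they took 4.14% of all gene counts in non-depleted replicate 1 (exact Clopper-Pearson 95% interval 4.13 to 4.14%) and 3.97% in non-depleted replicate 2 (3.96 to 3.97%). In insulin-depleted replicates 1 and 2 the insulin share was 0.195% (0.193 to 0.197%) and 0.264% (0.263 to 0.265%). These intervals cover counting error only, and most low counts were even, which makes them too narrow if fragments added 2 counts each. The mean insulin share was 4.05% ± 0.122 (SD, n = 2) without and 0.230% ± 0.0484 (SD, n = 2) with depletion, a 17.7-fold difference. Both insulin-depleted libraries lay below both non-depleted libraries, and 2 against 2 libraries cannot give an exact two-sided permutation p below 0.333, which was the value reached.

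Ins1 fell further than Ins2. Ins1 (ENSMUSG00000035804, chromosome 19, 52264297 to 52265476, plus strand, GRCm38) fell from 10223 ± 1811 to 111 ± 11.5 TMM-scaled CPM (SD, n = 2 each). Its log2 fold change was -6.52 (SE 0.19, edgeR quasi-likelihood test, adjusted p = 0.00236), a 91.9-fold lower level with a 95% interval of 66.0 to 128. Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381 as annotated, minus strand, GRCm38) fell from 31192 ± 64.9 to 2136 ± 439 CPM (SD, n = 2 each). Its log2 fold change was -3.87 (SE 0.17, edgeR adjusted p = 0.0114), a 14.6-fold lower level with an interval of 10.9 to 19.6. Of the 31-base stretches of Ins1 transcripts, 4.55% were found unchanged in Ins2.

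As a result, Ins2 counts outnumbered Ins1 counts by 3.10 ± 0.543 to 1 in non-depleted libraries and by 19.1 ± 1.97 to 1 in insulin-depleted libraries (SD, n = 2 each, exact two-sided permutation p = 0.333, the smallest these libraries allow). Ins2 was the most abundant gene of the non-depleted group, with 3.05% ± 0.0403 of counts, and Ins1 ranked 4 with 0.999% ± 0.162 (SD, n = 2). After depletion Iapp, which encodes the beta-cell peptide amylin, led with 1.80% ± 0.0639 of counts, followed by the glucagon gene Gcg with 1.19% ± 0.112 (SD, n = 2). The share of the 10 most abundant genes of each library was 10.4% ± 0.236 without and 7.28% ± 0.436 with depletion (SD, n = 2, exact two-sided permutation p = 0.333).

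**Figure D1:**
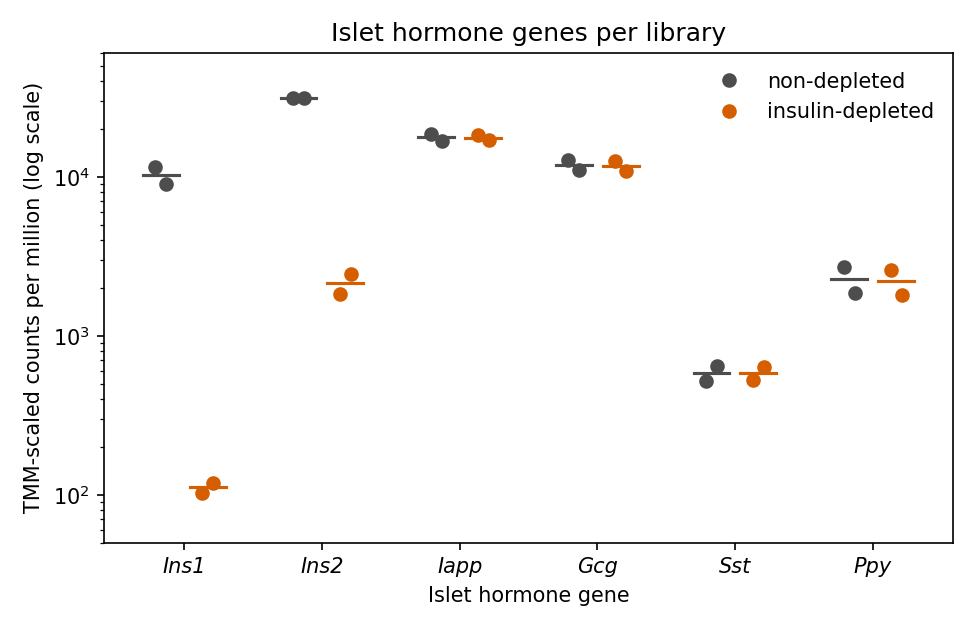
TMM-scaled CPM (log axis) of 6 islet hormone genes in each library, with points for single libraries and lines for group means. Ins1 had means of 10223 and 111 and Ins2 of 31192 and 2136 without and with depletion, while the points of Iapp, Gcg, Sst and Ppy overlapped between groups.

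The next question was whether genes other than insulin changed. In the model on group alone, Ins1 and Ins2 were the only genes past the threshold among 19723 tested. There, 0 genes were higher and 2 lower in insulin-depleted libraries (edgeR, adjusted p under 0.05). DESeq2 and limma-voom on group alone also gave 0 higher and 2 lower. With a term for the replicate number in edgeR, 2 genes were higher and 7 lower, with Ins1, Ins2 and Hadh among the lower ones. Libraries with the same number deviated together, but the labels do not state that they share an animal. At an unadjusted edgeR p under 0.05, 36 other genes were higher and 44 lower, and the smallest adjusted p among them was 1.00. These genes are far fewer than the share of 0.05 that a calibrated test gives without any change. The test on group alone was thus conservative here, and its spread includes the difference between replicate numbers. Of 4653 other genes with a mean of at least 50 CPM, 97.9% had a log2 fold change within 0.1 of 0, and the median half-width of their 95% intervals was 0.23. The test was also run on counts simulated with the same depth and dispersion. It recovered 6.00% of genes changed 2-fold, 78.0% of genes changed 4-fold and 94.0% of genes changed 16-fold. These libraries were drawn independently, so same-numbered ones did not deviate together as they did in the data. With a term for the replicate number in both simulation and test, 72.0% of genes changed 1.2-fold and 100% of genes changed 2-fold were recovered. In both simulations the changed genes were drawn from those with a mean of at least 5 CPM. Of the 19721 other genes tested, 11552 reached that level, and recovery below it was not measured. Both insulin-depleted libraries lay above both non-depleted ones for 9.70% of the other genes and below for 9.88%. With no change and libraries that differ independently, each share would be 16.7%. Same-numbered libraries deviated together here, so these shares do not measure a change.

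Among genes with a mean of at least 5 CPM, those with the smallest unadjusted p in each direction are given as values. None of them passed the correction in the model on group alone. With a term for the replicate number, Hadh, Gm10925 and Gm28437 did. Among those lower in insulin-depleted libraries were Fancf (log2 fold change -0.55), Cox11 (-0.42), Zbtb45 (-0.32) and Hadh (-0.26). Fancf, Cox11 and Zbtb45 overlap other annotated genes, and no source used here states whether strand was used in counting, so their reads are uncertain. Hadh, a mitochondrial fatty acid oxidation enzyme (ENSMUSG00000027984, chromosome 3, 131233419 to 131272101, minus strand, GRCm38), had 177 ± 17.7 CPM without and 147 ± 14.3 CPM with depletion (SD, n = 2). Its 95% interval on the log2 scale ran from -0.54 to 0.02. Higher were Gm12346 (0.48), Rps24-ps3 (0.42), Gm9794 (0.38), Gm10925 (0.34) and Gm28437 (0.30). All of these are annotated pseudogenes with 75.5 to 100% of their 31-base stretches in another gene, so their counts are uncertain too.

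**Figure D2:**
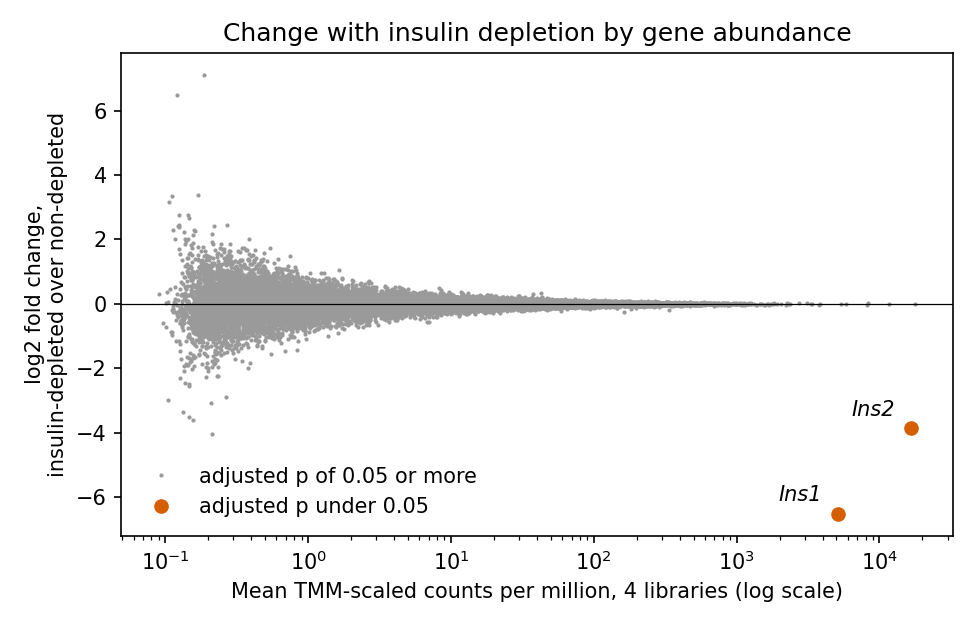
Log2 fold change of insulin-depleted over non-depleted libraries against the mean TMM-scaled CPM over 4 libraries (log axis), 1 point per gene tested. Ins1 (-6.52) and Ins2 (-3.87), in orange, are the 2 genes with an adjusted p under 0.05, and the spread of the other genes is widest at low abundance.

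Other endocrine genes kept levels close to those of non-depleted islets, with no member of these lists past the test over all genes or adjusted over the list alone. Of 8 other islet peptide hormones, 3 had a log2 fold change above 0 and 5 below, with a median of -0.01. Iapp had 17727 ± 1195 CPM without and 17598 ± 812 CPM with depletion, and Gcg had 11833 ± 1202 and 11666 ± 1222 CPM (SD, n = 2). The somatostatin gene Sst had 584 ± 87.8 and 581 ± 80.2 CPM, and the pancreatic polypeptide gene Ppy 2271 ± 597 and 2193 ± 548 CPM. Log2 fold changes were 0.02 for Pyy, 0.17 for Npy, 0.10 for Cck and -0.11 for Ghrl, and the last 3 had wide errors (SE 0.71, 0.33 and 0.64). Of 22 beta-cell identity genes, 13 were above and 9 below 0, within -0.12 to 0.09. In this list G6pc2, a glucose-6-phosphatase of beta cells, had 574 ± 12.3 and 578 ± 12.1 CPM, and the GLP-1 receptor gene Glp1r 462 ± 121 and 463 ± 111 CPM. Of 18 genes of secretory granules and prohormone processing, 8 were above and 10 below 0, within -0.07 to 0.05. The granule genes Chga and Scg2 had log2 fold changes of -0.03 and -0.0041. The 9 alpha-cell markers (median -0.04) and 8 delta- and gamma-cell markers (median -0.03) lay within -0.18 to 0.05. The alpha-cell marker Ttr had a log2 fold change of -0.04. Of 4 tested members of the insulin and relaxin superfamily other than Ins1 and Ins2, 2 were above and 2 below 0, with values of 0.08 for Igf1 and 0.23 for Insl3. The members below 0, named after their values were seen, were Igf2 (-0.14) and Insl6 (-0.88). Insl3, Igf2 and Insl6 lay under 1 CPM, and Insl3 overlaps Jak3.

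Markers of the other cell types of an islet preparation gave the same picture, with 0 genes called in any list. Acinar-cell markers, which come from the digestive tissue around islets, had a median log2 fold change of -0.01, with 9 of 22 above and 13 below 0. The lipase gene Pnlip had 2649 and 983 CPM in non-depleted replicates 1 and 2, and 2673 and 986 CPM in insulin-depleted replicates 1 and 2. The chymotrypsinogen gene Ctrb1 had 3019, 1110, 2992 and 1109 CPM in the same order. Acinar transcripts therefore differed between the libraries of each group far more than between groups. The medians of the 10 ductal, 13 endothelial and 12 stellate and fibroblast markers were -0.02, -0.01 and -0.02. Examples were Krt7 (-0.04) and Spp1 (-0.01) for duct, Kdr (0.02) and Flt1 (-0.01) for endothelium, and Sparc (-0.01) and Vim (-0.02) for stroma. Medians of 13 immune-cell and 6 Schwann-cell markers were both -0.06, with Cd68 at -0.11, Cd74 at 0.04 and Cryab at -0.07. The 5 erythroid markers had a median of 0.09 at low counts, with Hba-a1 at -0.27 and Hbb-bs at 0.12.

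Lists of cell functions also held no called gene in the model on group alone. With a term for the replicate number, the ribosomal protein genes Rps27, Rps13, Rps29 and Rps28 were called lower. Once GC correction was added to that model, Rps29 and Rps28 were no longer called. Of 80 genes of cytosolic ribosomal proteins, 69 lay below 0 with a median of -0.04, among them Rpl10 (-0.04) and Rpl4 (-0.01). The nuclear-encoded respiratory chain had 53 of 77 members below 0 and a median of -0.05, with Atp5b at -0.02 and Atp5a1 at 0.02. Of 13 mitochondrially encoded mRNAs, 7 were above and 6 below 0, within -0.04 to 0.30, with mt-Co1 at 0.01 and mt-Cytb at -0.02. The highest values, named after they were seen, were those of mt-Atp6 (0.30), mt-Co2 (0.29) and mt-Co3 (0.21), which did not pass the test and share nearly all of their sequence with other annotated genes. The 20 endoplasmic reticulum stress genes stayed within -0.08 to 0.05, with Hsp90b1 at 0.02 and the chaperone gene Hspa5 at 0.0012. The 19 immediate early and dissociation stress genes had a median of -0.01, with Socs3 at -0.06 and Junb at -0.02. The 15 cell cycle genes had a median of 0.05, with Pcna at 0.11 and Mcm4 at 0.10. The list of 36 replication-dependent histone genes, taken by name pattern, had 19 above and 17 below 0, with Hist1h1c at -0.03. The pattern also took in H1f0 (0.0078), a linker histone gene that is not replication-dependent. The 8 nuclear-retained long noncoding RNAs had a median of 0.01, with Malat1 at -0.02 and Meg3 at -0.04.

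On group alone, none of the 21 lists passed camera (adjusted p from 0.762 to 0.949). None passed with an estimated correlation (smallest adjusted p = 0.974) or fry (smallest adjusted p = 0.999) either. With a term for the replicate number, cytosolic ribosomal proteins passed camera, and no list passed with an estimated correlation. In either model, the test with an estimated correlation takes its degrees of freedom from the 4 libraries alone. It could therefore hardly pass, and its failure does not weigh against the camera call. That call rests on the preset correlation of 0.01, while 0.17 was estimated for this list. In 6 lists, among them the hormones and beta-cell identity, the median and the direction of camera differed in sign. No list member reached an unadjusted p under 0.05 on group alone (edgeR, 0 members), in a test that was conservative here. Leaving out 1 library gave 1 to 3 called lists. The acinar-cell list passed whichever library was left out, the ribosomal protein list when any library other than insulin-depleted replicate 2 was left out, and the respiratory chain list without insulin-depleted replicate 1 or without non-depleted replicate 2. The acinar-cell median was 0.68 without non-depleted replicate 1 or insulin-depleted replicate 2, and -0.67 and -0.66 without non-depleted replicate 2 and insulin-depleted replicate 1.

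**Figure D3:**
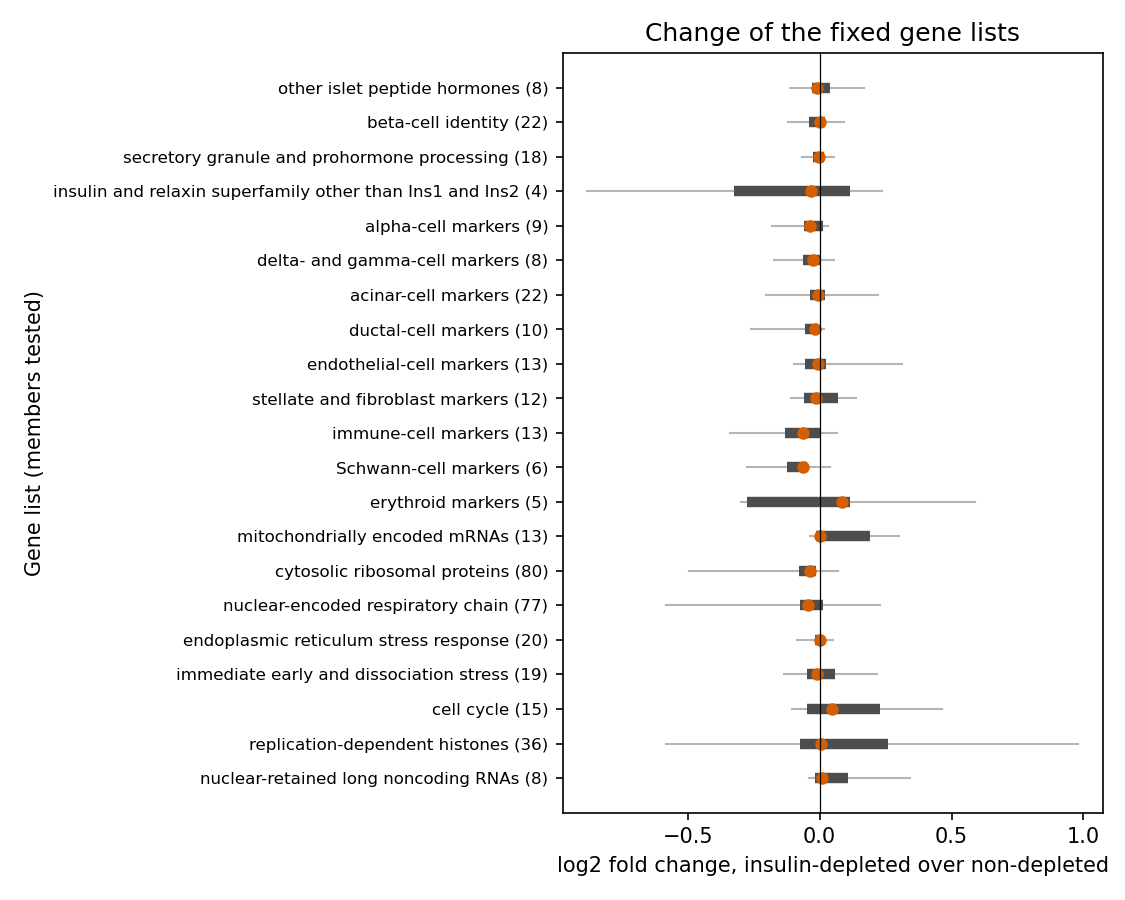
Log2 fold change of insulin-depleted over non-depleted libraries for the members of 21 gene lists, with points for medians, thick bars for interquartile ranges and thin lines for the whole range. Medians lie between -0.06 (immune-cell and Schwann-cell markers) and 0.09 (erythroid markers), and 0 lists passed camera on group alone.

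The last question was what the freed reads went to. Genes other than Ins1 and Ins2 received 959471 ± 1217 CPM (without TMM scaling) in non-depleted and 997704 ± 484 CPM in insulin-depleted libraries (SD, n = 2), a ratio of 1.04. This share is the remainder of the insulin share and adds no test of its own. Mitochondrial genes took 2.10% ± 0.185 and 2.19% ± 0.184 of counts (SD, n = 2), a difference smaller than the spread between replicates. Their share rose from 1.97 to 2.06% in libraries numbered 1 and from 2.23 to 2.32% in those numbered 2. The ratio of group means was 1.04, as for all genes outside insulin. With all libraries thinned to 19316173 counts, 16406 ± 65.1 genes had at least 10 counts without and 16600 ± 21.7 with depletion (SD, n = 2), a difference of 193.6 genes that exceeded the spread between replicates (exact two-sided permutation p = 0.333). Thinning took no counts from insulin-depleted replicate 1, and counts of 2 to 9 were even in 80.01 to 84.01% of genes in the 4 libraries, so that thinning single counts treated this library differently. With counts thinned in twos, an alternative chosen after seeing the data, the difference was 157.9 genes at 5 or more pairs of counts. At a minimum of 1 count the sign turned, with a difference of -736.2 genes.

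Profiles of other genes were compared by their spread. The SD over 19721 genes of the difference between group means of log2 CPM was 0.35. The SD of the log2 ratio was 0.55 between the 2 non-depleted and 0.71 between the 2 insulin-depleted libraries. The first value compares means of 2 libraries and the others single libraries. Each group holds both replicate numbers, so a difference that goes with the number cancels in the first value. Over the 4 combinations of single libraries from different groups the SD ranged from 0.37 to 0.71. With a mean of at least 5 CPM the 3 values were 0.08, 0.29 and 0.30 over 11552 genes. Between single libraries of different groups, the SD was 0.14 and 0.09 at the same number and 0.28 and 0.30 at different numbers. Pearson's r of log2 CPM across those genes, which are not independent replicates, was 0.985 between non-depleted and 0.984 between insulin-depleted replicates. Chi-square values per degree of freedom between replicates were 51.0 in non-depleted and 32.7 in insulin-depleted libraries, which sets them against counting noise alone and does not show that they are independent animals. Such values grow with depth, which was lowest in insulin-depleted replicate 1, so they do not rank the groups. Fragments that add 2 counts each would also raise them.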

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

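Alternatives with pairs of counts thinned together, counts divided by 2, thinning to 9658086 counts and thinning before the edgeR fit were chosen after seeing the data. Under all 17 alternatives run for each, Ins1 and Ins2 stayed lower and past the threshold, with adjusted p of up to 0.0115 for Ins1 and 0.0432 for Ins2. Of these, 4 leave 1 library in a group and take the spread from the other group alone, so their p-values carry less. Without each library in turn, the log2 fold changes of Ins1 and Ins2 ranged from -6.69 to -6.33 and from -4.10 to -3.67. The insulin share (differences of -3.91 to -3.74 points) and the ratio of counts outside the insulin genes (1.039 to 1.041) kept their direction. The count of 0 genes higher and 2 lower held in 16 of 18 alternatives. The exceptions add the replicate number to the model as a block. With the replicate block, 2 genes were higher (Gm10925 and Gm28437) and 7 lower (Ins1, Ins2, Hadh, Rps27, Rps13, Rps29 and Rps28). With the replicate block and GC correction, 2 were higher and 5 lower, as Rps29 and Rps28 were no longer called. These genes were named after their values were seen. Libraries with the same number deviated together (correlation 0.845 across 11552 genes), with an SD of log2 ratios between groups of 0.14 for number 1 and 0.09 for number 2 at 5 CPM, but the labels do not state that they share an animal, and with 2 numbers the block is not taken as a pairing. With it, 1 gene list passed camera (cytosolic ribosomal proteins), and 0 with an estimated correlation, a test that could hardly pass with so few libraries. Leaving out 1 library gave 1 to 3 called lists and the other 6 alternatives gave 0. Leaving out a library unbalances the replicate numbers between groups, and the sign of the acinar-cell median depended on both the number and the group left out. The median was 0.68 without non-depleted replicate 1 or insulin-depleted replicate 2, -0.67 without non-depleted replicate 2 and -0.66 without insulin-depleted replicate 1. The ribosomal protein (0.14, 0.12, -0.20 and -0.20) and respiratory chain medians (0.04, 0.04, -0.11 and -0.11) turned alike, so these calls go with the imbalance.

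The difference in genes detected, 193.6 at 10 counts, depended on the minimum and the depth. It was 47.4 at 50 counts, 74.9 after thinning to 1931617 counts, 101.4 after thinning to 9658086 counts, and 147.5 to 239.6 without each library in turn. It reversed to -736.2 at 1 count, to -1069.5 with no thinning, where the depth of insulin-depleted replicate 1 sets the sign, and to -80.3 at 1 pair of counts thinned together. It was 40.4 at 1 pair with pairs thinned in all 4 libraries to a lower shared depth. At 1 count insulin-depleted replicate 1, the only library not thinned, had 22705 genes against 24150.1 to 24337.3 in the others, and with pairs thinned together it had 22705 against 22848.2 to 22932.85. With all 4 libraries thinned in pairs to the lower depth it had 20744.85, above 20701.35 in non-depleted replicate 1, and the sign was no longer reversed. Pairs and depth were changed together in that last setting, so their shares in the cause were not tested. The SD over other genes of the difference between group means of log2 CPM fell from 0.35 to 0.083 at 5 CPM and 0.040 at 50 CPM. The cause was not tested. Depth limits what can be said of genes below 0.155 CPM, which is 3 counts in the smallest library. The main test, with 2 libraries per group and no term for the replicate number, seldom detected a 2-fold change in simulated counts. With that term in both simulation and test, 50 of 50 genes changed 2-fold were recovered. In both simulations the changed genes had a mean of at least 5 CPM.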

Other observations

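All patterns of this part were picked after the values were seen. For Hadh, insulin-like sites, the trend in acinar markers and shared sequence in pseudogenes, the test and its limits were set before the result of that test was seen. The tests of shared preparation and shared handling, and those of the trend and of low abundance in pseudogenes, were chosen only after the result was seen.

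Among 13 mitochondrially encoded mRNAs, 5 had at least 95% of their 31-base stretches in other annotated genes, and these had mean levels of 3.37 to 19.1 CPM. They were mt-Co2, mt-Co3, mt-Atp6, mt-Nd4l and mt-Nd3, while mt-Co1, with 63.9% of its stretches shared, had 8313 CPM. Among the 5, mt-Co2, mt-Co3, mt-Atp6 and mt-Nd4l were higher in both insulin-depleted libraries than in the non-depleted library of the same number. Their mean log2 ratios were 0.29, 0.20, 0.31 and 0.19, and none passed the test. The ratio of mt-Nd4l in libraries numbered 1 was only 0.03. For mt-Nd3 the ratios were 0.08 in libraries numbered 1 and -0.08 in those numbered 2. A row of pseudogenes on chromosome 1 holds the copies, among them Gm10925 (24613974 to 24614651) at 42.6 CPM and Gm28437 (24613189 to 24613971) at 37.3 CPM, both fully shared. Counts of these mRNAs and of their nuclear copies can therefore not be read as transcript levels. The level of mt-Atp8 was also low, at 1.68 CPM with 7.47% shared. Shared sequence was sought in annotated transcripts only, so an unannotated copy would be missed. For that reason mt-Atp8 cannot decide whether low counts are specific to mRNAs with copies.

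More pseudogenes were higher than lower in both insulin-depleted libraries. Of 104 pseudogenes with a mean of at least 5 CPM, 49 were higher in both libraries than in the non-depleted library of the same number and 11 lower in both, with a median log2 ratio of 0.07 and none past the edgeR threshold. The highest median of 10000 lists of protein-coding genes matched on abundance was 0.038, which argues against low abundance but does not exclude it. These lists took genes as independent, while related pseudogenes can draw on the same reads, so the medians of the lists may spread too little. A trend with GC content or transcript length does not account for the pattern, since its removal left a median of 0.075. Shared sequence is a candidate explanation: the 67 pseudogenes with at least 50% of their sequence in another gene had a median of 0.13 and the 14 with under 10% -0.03, a difference of 0.16 (permutation p = 0.0021). Reads may thus have been assigned differently between near-identical genes in the 2 kinds of library, for example through fragment length, since only the non-depleted column names carry a tag that reads as size selection, which was not tested, and no biological explanation was tested. The permutation took pseudogenes as independent, but related copies can draw on the same reads, such as the 6 mitochondrial copies on chromosome 1. Its p-value may therefore be too small.

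Hadh was the lowest of 4651 genes with a mean of at least 50 CPM, at a log2 ratio of -0.26 in libraries numbered 1 and -0.27 in those numbered 2, against -0.19 for the next lowest. Hadh transcripts held 0 of their 734 NGG-flanked sites within 3 mismatches of an insulin site, and the closest had 4. This argues against cleavage within that limit only, since looser matches were not tested. Among 11552 genes with a mean of at least 5 CPM, 328 with a site within 3 mismatches differed in median from 11224 without by -0.00077 (permutation p = 0.838). The 21 genes with a site within 2 mismatches had a median of -0.013. All 377 insulin sites were compared rather than the guides used, so these medians would not show cleavage of a few genes. The log2 ratio of Hadh was -0.26 after removing the trend with GC content and transcript length, and the beta-cell identity list had a median of 0.0027, which argues against a lower share of beta-cell RNA. The guide sequences were not used here, so a guide that cuts Hadh for other reasons stays open, and so does size selection or another preparation step that differs with depletion.

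Acinar markers followed the replicate number. All 21 with a mean of at least 5 CPM were lower in number 2 than in number 1 in both groups, with median log2 ratios of -1.37 (non-depleted) and -1.33 (insulin-depleted), or 2.58-fold and 2.52-fold. A trend with GC content or transcript length does not account for this, since the median nearer to 0 was -1.32 after its removal. The ratios of the 2 groups differed by a median of 0.030 per gene, so same-numbered libraries may come from one islet preparation with its own share of acinar tissue. Libraries that share a number may also have been handled or sequenced together, which cannot be told apart from this, because 0 labels separate handling from number.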
